A study of Zea mays with 19 samples.

How the data were processed

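Small RNA libraries were made from embryos of 2 maize inbred lines, each sample holding the embryos of 5 seeds, per the labels. Yu82 germinates early and Yu537A germinates late, and both come from the population Yuzong5. The 18 libraries form 6 groups of 3 biological replicates: the early line at 6 h and 53 h after imbibition, the late line at 6 h, 53 h and 78 h, and the late line with gibberellin (GA3, 400 mg/L) at 53 h. The labels also state that seeds of Yu537A were pretreated with GA3 without saying in which groups, and the series design names 1 group as treated. The other Yu537A groups were taken as untreated on that basis. A degradome library, which captures the ends of cleaved transcripts, stands in no group.

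The authors' deposited miRNA table lists expected counts, in which the reads of a sequence are divided over the precursor entries that share it. These entries carry equal values. Among values above 0 of sequences on more than 1 entry, 43.9% were whole (within 0.01) before and 88.6% after summing. A second set of columns holds a deposited signal that equals the expected counts times 1 factor per library set by the authors. How that factor was set is not given in the sources used here. In the degradome table, the authors give read counts per cleavage site, 2 further columns of signal (deposited as normalized reads and a scaled abundance), a p-value per site that the authors do not describe as adjusted, an alignment score of the small RNA on the transcript (deposited as a penalty), and an other measure, the deposited cleavage category from 0 to 4. The matching tools, their versions and the genome build are not given in the sources used here. Both tables were held in part: 9 lines of the miRNA table and 5176 lines of the degradome table were empty.

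The 782 entries of the miRNA table were summed to 536 unique sequences and rounded. Of these, 9 sequences had the same values in every library as another sequence and were merged, which left 527: 96 with a maize name, 150 named after another species and 281 candidates without a miRBase name. In most libraries the smallest listed sequence total was 4 counts. Many sequences, zma-miR166b-5p and zma-miR2118b among them, had no listed count below 8. A sequence listed at 0 was thus not shown to be absent, and may have had 4 counts or more. Folds against a group at 0 in all 3 libraries were computed against 4 counts per library and are written as lower bounds. They hold as bounds only if listing began at 4 counts, and would be smaller if it began higher. Library totals ran from 42803 counts (early line at 53 h, replicate 3) to 818252 (late line at 53 h, replicate 1). Reads carried no molecular identifiers, so totals speak for counting error alone.

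Counts were tested in edgeR 4.0.16 under R 4.3.3 with TMM scaling, a filter by expression with a minimum count of 10, 1 model with a mean per group, and the quasi-likelihood F test (two-sided). The filter kept 219 sequences. Adjusted p-values are Benjamini-Hochberg values over these 219, with 0.05 as the threshold. Standard errors are the log2 fold change over the square root of F. Levels are given as CPM, counts scaled by the TMM totals. The same test was run on the sums of 48 families. The 11 lists of families were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. They are phase change (miR156, miR157, miR529, miR172), GAMYB and TCP targeting (miR159, miR319), auxin signalling (miR160, miR167, miR390, miR393), meristem and growth factors (miR164, miR166, miR171, miR394, miR396), phosphate and sulphate (miR395, miR399, miR827), copper and redox (miR397, miR398, miR408, miR528), NF-YA targeting (miR169), small RNA pathway (miR162, miR168), reproductive triggers of phased siRNAs as markers of another tissue (miR2118, miR2275, miR482), other named families, and unnamed candidates. Family shares of the counts were compared by a two-sided exact permutation test. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for the tables and plots.

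The 9 comparisons (6 main and 3 secondary), the lists, the tests and the rule for named miRNAs were fixed before the data were examined. The rule takes, for a main comparison, up to 6 sequences per direction with the largest change among those past the threshold, with a mean of at least 10 CPM and no overlap between the groups' libraries, at most 1 per family and arm. A secondary comparison takes up to 3 per direction. The rule adds the 2 most abundant sequences of each list and the 10 most abundant of all. For each named miRNA, up to 3 degradome sites of category 0 or 1 with the lowest p are taken. Sequences named outside the rule are given as such.

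The labels do not say whether replicates with equal numbers belong together. The residuals of like-numbered libraries correlated above 0.1 in all 3 pairs for 1 comparison, the late line from 53 h to 78 h (0.454, 0.205 and 0.304), where a fit with the replicate number as a block called 0 sequences, as did the fit without it. The fit was tested on simulated data with the depth and spread of these libraries, in 5 runs. For GA3 at 53 h it recovered 6% of 100 simulated 4-fold changes and 41% of 100 16-fold changes, with 0 false calls among 895 unchanged sequences. In the other pairwise comparisons it recovered 8% to 15% and 36% to 45%, with at most 2 false calls each. Camera gave an unadjusted p under 0.05 for 8 of 8 lists whose members were all raised 16-fold and for 0 of 8 unchanged lists. The real lists were called by p adjusted over all lists, which this did not test. Simulated sequences varied independently, so this does not give the rate of false list calls in the real data. Regrouping the real libraries for GA3 at 53 h gave up to 5 list calls. The common biological coefficient of variation was 0.978. For the 106 sequences with a mean of at least 100 CPM, the median standard error of a log2 fold change was 0.71 for GA3 at 53 h and 1.02 for the interaction.

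The alternatives fixed before the data were examined were RLE scaling, library totals alone, no filter or a minimum mean of 10 CPM, DESeq2 1.42.0, limma voom, a replicate block, a model with the compared groups alone, named miRNAs alone, an added log2 fold threshold of 1, and each replicate left out in turn. Chosen after seeing the data were 1 entry per sequence, the authors' factors, thinning of each library to 42803 counts, and fits without early line 53 h replicate 3 or without the late line's replicates 3 at 6 h and 53 h. For the correlations with the GA3 effect, a minimum mean of 100 CPM and thinning were also chosen after seeing the data. Alternatives planned for a table with normalized values alone were not needed, since the table holds counts. The degradome library was left out of the comparisons because it belongs to no group. None of the 442 maize gene identifiers with a detected cleavage matched the reference table of symbols, so genes are given by identifier and by the term in the deposited table.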

Results

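Small RNAs were sequenced from embryos of an early germinating maize line (Yu82) and a late germinating line (Yu537A) during the first days after imbibition, with and without gibberellin (GA3) for the late line. Each of the 6 groups held 3 libraries. Totals ran from 159594 to 205117 counts for the early line at 6 h, from 42803 to 170287 for the early line at 53 h, from 105730 to 494727 for the late line at 6 h, from 98942 to 818252 for the late line at 53 h, from 156397 to 437074 for the late line at 78 h, and from 230424 to 464352 with GA3. Late-line replicates 1 and 3 at 6 h listed 113 and 124 sequences and replicate 3 at 53 h listed 108, against 378 in the deepest library.

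miR166, which targets class III HD-ZIP transcription factors, held 58.5% of all miRNA counts on average over the 18 libraries. Averaged in the same way, miR444, a grass family that targets MADS-box genes, held 8.04%, miR319 5.54%, miR408 5.34%, miR397 3.96% and miR396 2.99%. The order differs between the lines: group means ran from 0.950% (early line at 53 h) to 9.91% (late line at 78 h) for miR408 and from 0.352% (early line at 53 h) to 6.81% (late line at 6 h) for miR397. By the mean over all libraries the most abundant sequence was zma-miR166a-3p at 610167 CPM, with zma-miR444a at 60703 CPM, zma-miR408a_L-1 at 58823 CPM (group means from 6631 to 113778 CPM) and zma-miR319a-3p_R+1 at 53602 CPM. The first principal component of the log counts held 30.4% of the variance, and all 6 early-line libraries lay below all 12 late-line libraries on it.

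Whether GA3 changes the miRNAs of the late line was asked at 53 h, at a matched time. No sequence passed the test. The log2 fold changes of 21 abundant sequences of the lists ran from -1.31 to 1.36. This leaves out zma-miR2118b, with counts of 0, 8 and 0 with GA3 and of 0, 0 and 0 without. Over the 106 sequences with a mean of at least 100 CPM, log2 fold changes ran from -1.31 to 3.76. zma-miR408a_L-1, of a family that targets copper proteins, stood at 56893 ± 13874 CPM with GA3 and 57250 ± 13887 CPM without (SD, n = 3; log2 fold change -0.01, SE 0.73). zma-miR319a-3p_R+1, which targets TCP transcription factors, stood at 59778 ± 10459 and 54816 ± 12534 CPM (0.13, SE 0.36), and zma-miR166a-3p at 691818 ± 179012 and 732451 ± 269933 CPM (-0.08, SE 0.41). The signs of zma-miR408a_L-1 and zma-miR166a-3p turned positive with library totals alone. The lowest p belonged to zma-miR168b-3p_R+1, of the rarer strand of the family that targets the silencing protein ARGONAUTE1. It stood at 1670 ± 650 CPM with GA3 and 652 ± 65.9 CPM without (1.36, SE 0.46, adjusted p = 0.908 by the edgeR quasi-likelihood test). Of the 4 sequences of the small RNA pathway list it alone was higher when adjusted over the list alone (adjusted p = 0.0391).

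Of 219 sequences tested with edgeR under GA3, 0 were higher and 0 lower, 11 had an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. Without the low-count filter 2 were higher. The libraries of the 2 groups did not overlap for 21 sequences higher and 3 lower with GA3, together 11%. Chance gives 10% without ties and less with ties. Sequences at 0 in every library of both groups can never be counted. Of the 48 families 0 passed, and of the 11 lists 0 passed in camera, the lowest adjusted p being 0.108 for copper and redox and for the small RNA pathway. The GAMYB and TCP targeting list had 11 of 12 members with a positive log2 fold change and a median of 0.35 (camera adjusted p = 0.136). By the exact permutation test the share of counts was 6.41% with GA3 and 7.23% without for miR444, and 2.36% and 3.82% for miR396 (p = 0.1 each, the smallest that 3 against 3 allows, adjusted p = 0.3). With simulated 4-fold changes recovered at 6%, a change of that size was in most cases not detectable at this depth and spread.

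**Figure D1:**
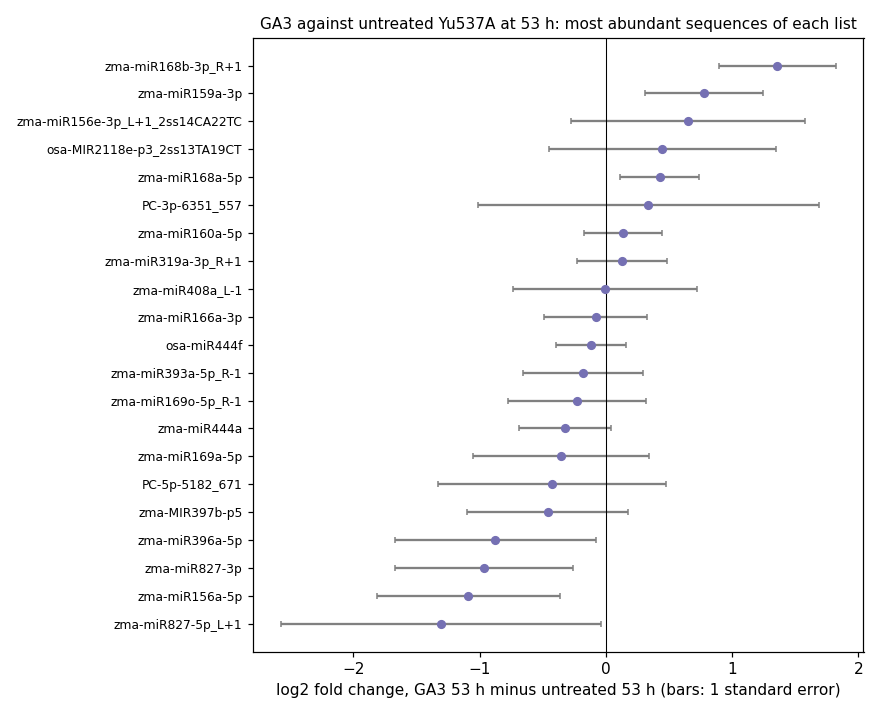
Log2 fold change between GA3-treated and untreated late-line embryos at 53 h (horizontal axis) for 21 abundant sequences of the fixed lists (vertical axis), with bars of 1 standard error and 3 libraries per group. Values run from -1.31 to 1.36, and 1 of the 21 lies more than 2 standard errors from 0. No sequence passed the adjusted test. zma-miR2118b, at 0 in the untreated libraries, is left out of the plot.

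How the lines differ soon after imbibition was asked at 6 h. Of the 15 copper and redox sequences, whose families target laccases, plantacyanins and other copper proteins, 6 were higher in the late line and 9 did not pass. Camera called the list (adjusted p = 1.69e-07), but not with an estimated correlation (adjusted p = 0.205 with an estimated correlation). zma-MIR397b-p5, with its precursor on chromosome 5 from 84610591 to 84610674 (build not given in the sources used here), stood at 74481 ± 34852 CPM in the late line and 4747 ± 2745 CPM in the early line (SD, n = 3; log2 fold change 3.97, SE 0.72, adjusted p = 0.0027). zma-miR408a_L-1 stood at 113778 ± 100095 and 11927 ± 8445 CPM (3.25, SE 0.79, adjusted p = 0.0175), and zma-miR528a-5p at 42854 ± 24261 and 6526 ± 2384 CPM (2.72, SE 0.63, adjusted p = 0.0124). zma-miR397a-5p and zma-MIR408a-p5 were listed at 0 in the early line, at least 16.6-fold and 7.11-fold lower there.

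At 6 h the early line in turn held more of 10 sequences. zma-MIR319b-p5, the arm opposite the TCP-targeting strand, stood at 2606 ± 65.3 CPM in the early line and 297.0 ± 86.6 CPM in the late line (log2 fold change -3.13 for late over early, SE 0.37, adjusted p = 4.51e-05). zma-miR159c-3p_L-1R-1, of a family that targets GAMYB transcription factors, was also lower in the late line (-2.14, SE 0.44, adjusted p = 0.0056). Both were named after their values were seen, and the call of zma-miR159c-3p_L-1R-1 ended without late-line replicate 1 (adjusted p = 0.0544) or replicate 3 (0.0636). bdi-MIR444d-p5_1ss2GA and zma-miR2118b, of a family that triggers phased siRNAs in flowers, were listed at 0 in the late line, at least 8.74-fold and 5.38-fold lower. So was the unnamed candidate PC-3p-12284_291, at least 9.64-fold lower. The call of zma-miR2118b ended when any 1 of the 6 libraries was left out.

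At 6 h, 6 of 219 sequences were higher and 10 lower in the late line by the edgeR quasi-likelihood test. By this test 63 had an unadjusted p under 0.05, and libraries did not overlap for 27.9%, where chance gives at most 10%. All 6 higher sequences were among the 15 of the copper and redox list, of which 10 were higher when adjusted over the list alone. The list's median log2 fold change was 3.08, or 2.72 with sequences at 0 set to their bound, against -0.36 for all sequences, and mtr-miR397-5p (-0.997) and mtr-miR398b (-1.63) had negative values. The 67 unnamed candidates, 5 of them lower and 62 not past the test, were also called lower (adjusted p = 0.0304, and 0.763 with an estimated correlation), and not with library totals alone. By family, miR397 (3.86, SE 0.58, adjusted p = 1.38e-04), miR408 (3.16, SE 0.72, adjusted p = 0.0057) and miR528 (2.58, SE 0.58, adjusted p = 0.0057) were higher and 0 lower. The calls of zma-miR408a_L-1 and zma-miR528a-5p ended without late-line replicate 3 (2.10 and 2.08) and without early-line replicate 1 (2.76 and 2.35) or 3 (3.12 and 2.75), as did those of the miR408 and miR528 families, and the 16 calls fell to 7, 9 and 9, while DESeq2 called 28 and limma voom 46. The call of zma-miR408a_L-1 also ended in a model with the compared groups alone (2.97, adjusted p = 0.0564) and that of zma-miR528a-5p with library totals (2.03, adjusted p = 0.0546). The median over all sequences moved from -0.36 to -1.03 with library totals, under which 5 sequences were higher and 18 lower.

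The same question was asked of the lines at 53 h. Of the 15 copper and redox sequences 9 were higher in the late line and 6 did not pass (camera adjusted p = 1.15e-07, and 0.192 with an estimated correlation). zma-MIR397b-p5 stood at 61395 ± 14644 CPM against 1997 ± 1977 CPM in the early line (SD, n = 3; log2 fold change 4.94, SE 0.75, adjusted p = 0.0012), zma-miR408a_L-1 at 57250 ± 13887 against 6631 ± 6324 CPM (3.11, SE 0.79, adjusted p = 0.0164), and zma-miR528a-5p at 24987 ± 5253 against 3591 ± 2411 CPM (2.80, SE 0.63, adjusted p = 0.0098). zma-miR397a-5p was listed at 0 in the early line, at least 7.22-fold lower. zma-miR827-3p, of a family that controls phosphate transport, and zma-miR393a-5p_R-1, which targets auxin receptors, were higher by 2.46 (SE 0.74, adjusted p = 0.0418) and 1.98 (SE 0.49, adjusted p = 0.016). Both calls ended with library totals (1.49 and 1.07, adjusted p = 0.0583 each), as did that of zma-miR408a_L-1 (2.36, adjusted p = 0.0541), and that of zma-miR827-3p also in a model with the compared groups alone (adjusted p = 0.0819) and with the replicate block (0.0775).

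miR159 was lower in the late line at 53 h. zma-miR159a-3p stood at 4766 ± 1949 CPM against 18110 ± 8822 CPM in the early line (log2 fold change -1.93, SE 0.48, adjusted p = 0.016), zma-miR159c-3p_L-1R-1 at 702 ± 358 against 4498 ± 1034 CPM (-2.69, SE 0.45, adjusted p = 0.0012), and zma-MIR319b-p5 at 750 ± 93.9 against 2859 ± 251 CPM (-1.93, SE 0.35, adjusted p = 0.0018). bdi-MIR444d-p5_1ss2GA was listed at 0 in the late line, at least 34.0-fold lower, and zma-miR2118b at least 13.7-fold lower. The call of zma-miR159a-3p ended without early-line replicate 1 (adjusted p = 0.0574) or 3 (0.122) and without late-line replicate 1 (0.114) or 2 (0.105), and that of zma-miR2118b without any of the same 4 libraries.

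At 53 h, 14 of 219 sequences were higher and 9 lower in the late line by the edgeR quasi-likelihood test. By this test 88 had an unadjusted p under 0.05, and libraries did not overlap for 36.1%, where chance gives at most 10%. The 15 copper and redox sequences had a median of 3.74, or 2.50 with sequences at 0 set to their bound, and 11 were higher when adjusted over the list alone. Of the 12 GAMYB and TCP targeting sequences 3 were lower and 9 did not pass, with 6 lower when adjusted over the list alone (median -1.36; camera adjusted p = 0.0245, and 0.252 with an estimated correlation). Families that passed were miR397 (4.68, SE 0.60), miR408 (2.92, SE 0.71), miR528 (2.60, SE 0.58), miR827 (2.21, SE 0.66), miR398 (1.83, SE 0.52) and miR393 (1.73, SE 0.44), all higher, and miR159 (-2.20, SE 0.50) and miR390 (-2.18, SE 0.64), both lower (adjusted p from 1.74e-05 for miR397 to 0.0205 for miR827 and miR390). All 6 sequences higher at 6 h were also higher at 53 h, where 0.384 would be shared by independent calls, and 7 of the 10 lower at 6 h were also lower, where 0.411 would be. These expected values treat all 219 sequences as independent and equally likely to be called. The 6 belong to miR397, miR408 and miR528 alone, and sequences of 1 family need not be independent. The 23 calls fell to 8 without early-line replicate 1 or replicate 3, the shallowest library, and to 14 without late-line replicate 2 or 3; without either of these early-line replicates the families miR408, miR528, miR398, miR827 and miR393 and the sequences zma-miR408a_L-1, mtr-miR408-3p_L-1R+2, zma-miR528a-5p, zma-miR827-3p and zma-miR393a-5p_R-1 lost their calls, and without replicate 3 so did miR159 and miR390. Calls also ended without late-line replicate 3 for miR408 (2.61), miR398 (1.56), miR390 (-1.82), zma-miR408a_L-1 (2.86) and zma-miR528a-5p (2.71), without replicate 2 for miR390 (-2.13) and zma-miR827-3p (2.44), and without replicate 1 for miR827 (1.68) and zma-miR827-3p (1.72). mtr-miR408-3p_L-1R+2 lost its call in 11 of 19 alternative fits. Among them were each late-line replicate left out, RLE scaling, library totals, the replicate block and the compared groups alone. DESeq2 called 50 and limma voom 75, and with library totals 6 were higher and 22 lower, as the median over all sequences moved from 0.01 to -0.78.

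**Figure D2:**
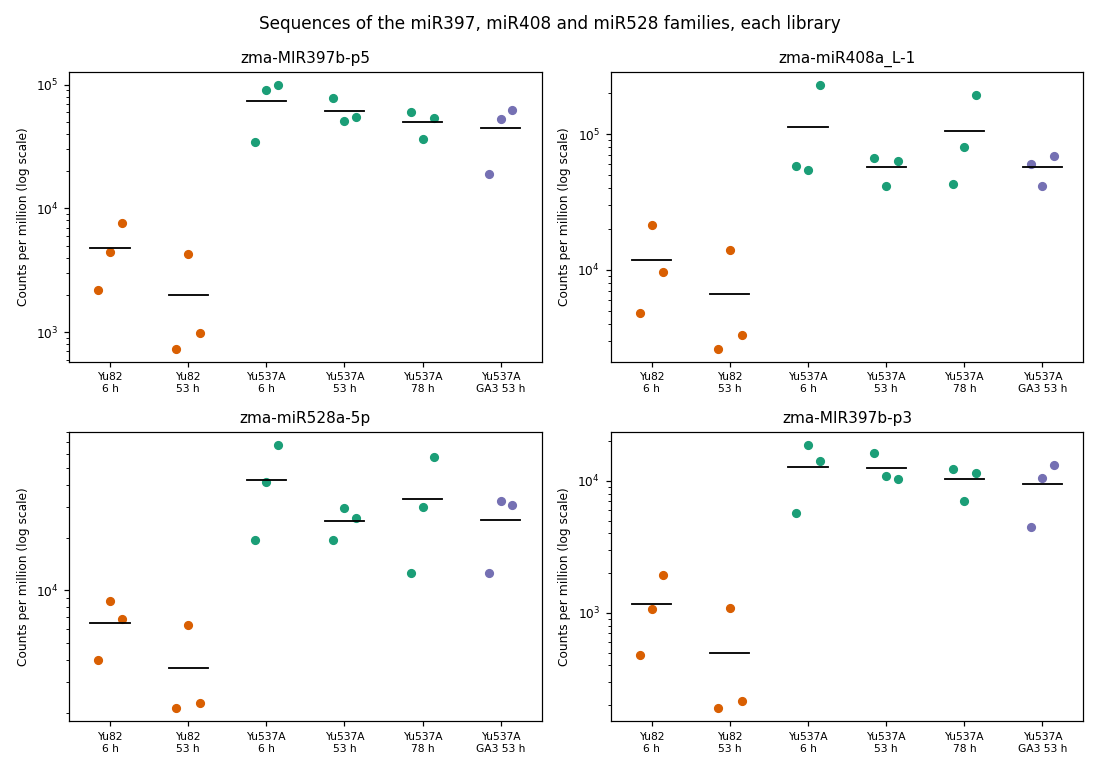
CPM on a log scale (vertical axis) in each library of the 6 groups (horizontal axis) for zma-MIR397b-p5, zma-miR408a_L-1, zma-miR528a-5p and zma-MIR397b-p3, with points for the 3 libraries of a group and a line at their mean. For zma-MIR397b-p5 the 6 early-line libraries lie between 736 and 7638 CPM and the 12 late-line libraries between 18892 and 98927 CPM.

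Change during germination was followed in the early line from 6 h to 53 h. The 4 sequences that passed were 5p sequences of miR159 and miR166, usually the rarer strand of these miRNAs. zma-miR159a-5p_R-1 was listed at 0 in all 3 libraries at 6 h and stood at 1407 ± 245 CPM at 53 h, at least 81.3-fold higher (SD, n = 3; adjusted p = 5.11e-05). zma-MIR159f-p5 stood at 623 ± 109 CPM at 53 h, at least 36.0-fold higher (adjusted p = 1.69e-04), and zma-miR166a-5p at 372 ± 184 CPM, at least 21.5-fold higher (adjusted p = 0.0041). zma-miR166b-5p stood at 137 ± 13.7 CPM, at least 7.89-fold higher (adjusted p = 0.0472). zma-MIR159f-p5 and zma-miR166b-5p were named after their values were seen. Other miR166 5p sequences had reads at 6 h: aly-MIR166a-p5_2ss13CG20AC had 19, 13 and 20 counts at 6 h and 0, 17 and 0 at 53 h, and zma-miR166c-5p had 10 counts in 1 library at 6 h.

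These 4 of 219 sequences rose in the early line and 0 fell by the edgeR quasi-likelihood test. By this test 32 had an unadjusted p under 0.05, and libraries did not overlap for 26.9%, where chance gives at most 10%. Of the 12 GAMYB and TCP targeting sequences 2 rose and 10 did not pass, with 3 higher when adjusted over the list alone, and both that rose are miR159 5p sequences. The list's median was 0.69, against -0.29 for all sequences (camera adjusted p = 3.16e-04, and 0.128 with an estimated correlation). Of the 48 families 0 passed. The call of zma-miR166b-5p ended when any 1 of 5 libraries was left out (6 h replicates 1, 2 and 3, and 53 h replicates 1 and 3). That call also ended with the replicate block (adjusted p = 0.0855). In settings chosen after seeing the data, it ended with 1 entry per sequence (0.0752) and without the late line's replicates 3 at 6 h and 53 h (0.0595). Without replicate 2 at 53 h the 4 calls became 5 higher and 8 lower. DESeq2 called 12 and limma voom 26.

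In the late line from 6 h to 53 h, 3 of these 4 sequences rose. zma-miR159a-5p_R-1 went from 0 at 6 h to 991 ± 605 CPM at 53 h, at least 34.3-fold higher (SD, n = 3; adjusted p = 1.31e-04). zma-MIR159f-p5 reached 156.9 ± 114.8 CPM, at least 5.42-fold higher (adjusted p = 0.0022), and zma-miR166a-5p 271 ± 206 CPM, at least 9.35-fold higher (adjusted p = 0.0085). ppt-miR894_L-3R+1, named after a moss family, fell from 2917 ± 1841 to 537 ± 289.7 CPM (log2 fold change -2.44, SE 0.50, adjusted p = 0.0085).

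In the late line 3 of 219 sequences rose and 1 fell by the edgeR quasi-likelihood test. By this test 20 had an unadjusted p under 0.05, and libraries did not overlap for 7.3%, where chance gives at most 10%. All 3 that rose were also among the 4 of the early line. If all sequences were independent and equally likely to be called, 0.055 would be shared, but sequences of 1 family need not be independent. Of the 12 GAMYB and TCP targeting sequences 2 rose, again miR159 5p sequences, and 10 did not pass, with 4 higher when adjusted over the list alone (median 0.87, or 0.31 with sequences at 0 set to their bound; camera adjusted p = 1.28e-04, and 0.0967 with an estimated correlation). Camera also called the 48 sequences of other named families lower, of which 1 fell and 47 did not pass (adjusted p = 0.0122, and 0.225 with an estimated correlation). By family miR894 fell (-2.39, SE 0.56, adjusted p = 0.0226). Without replicate 3 at 6 h the 4 calls became 2, since ppt-miR894_L-3R+1 (adjusted p = 0.149) and zma-miR166a-5p (0.0748) no longer passed. The call of zma-miR166a-5p also ended without replicate 1 (0.0508) or 2 (0.0788) at 6 h, that of ppt-miR894_L-3R+1 without replicate 1 (0.0518) or 2 (0.0956) at 53 h, and 1 call was left in a model with the compared groups alone. The call of zma-MIR159f-p5 ended after thinning each library to the same total (5.99, adjusted p = 0.0545), a setting chosen after seeing the data.

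**Figure D3:**
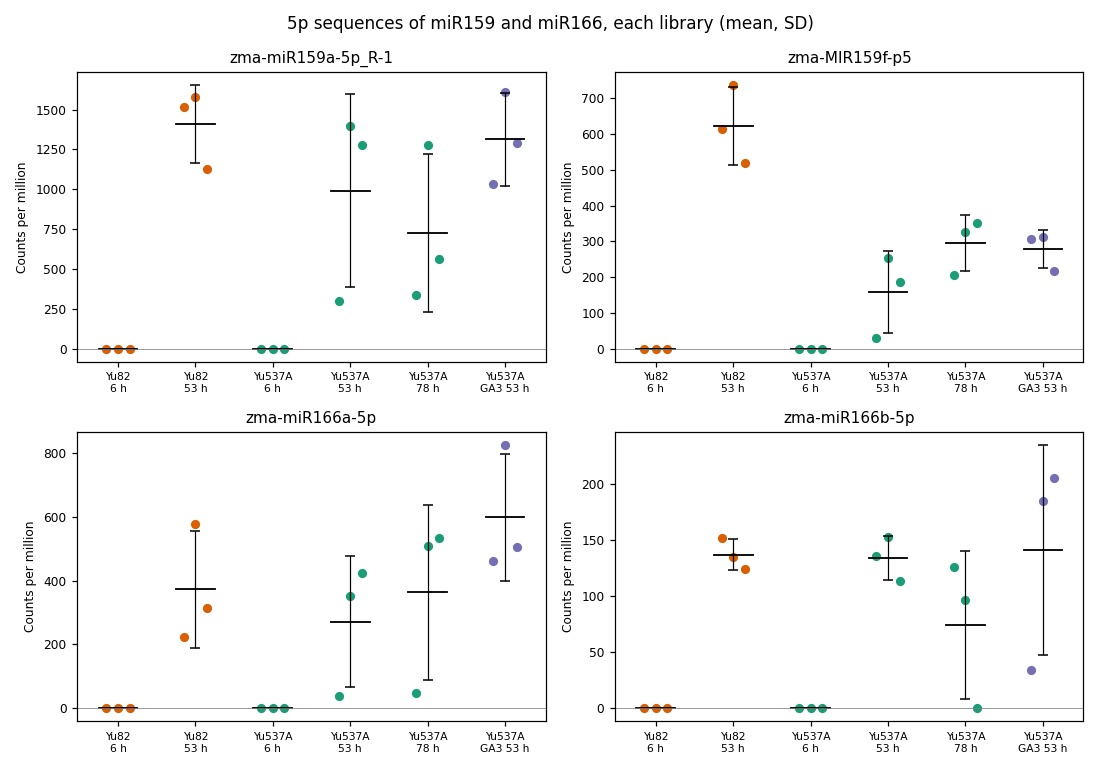
CPM (vertical axis) in each library of the 6 groups (horizontal axis) for zma-miR159a-5p_R-1, zma-MIR159f-p5, zma-miR166a-5p and zma-miR166b-5p, with points for the 3 libraries of a group, a line at the mean and a bar of 1 SD. All 6 libraries at 6 h are at 0 for each of the 4 sequences, while zma-miR159a-5p_R-1 averages 1407 CPM in the early line and 991 CPM in the late line at 53 h.

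Whether the lines differ in their change over time was tested as an interaction. No difference between the lines' changes passed the edgeR quasi-likelihood test: 0 of 219 sequences were called, with 17 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma voom. For the 4 5p sequences of miR159 and miR166 that were at 0 in all 6 libraries at 6 h, the interaction could not be estimated (SE from 45.7 to 2283), so whether their rises differ is open. Of the families and lists 0 passed. The median difference over all sequences was 0.66, and it stayed between 0.43 and 0.66 under the 4 scalings. Without early-line 53 h replicate 2, 5 sequences were called.

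Later germination of the untreated late line was covered from 53 h to 78 h. No sequence passed the test. Among the sequences of the rule for named miRNAs, the lowest p belonged to zma-miR168a-5p, which targets ARGONAUTE1 and stood at 2956 ± 437 CPM at 78 h and 1448 ± 169.3 CPM at 53 h (SD, n = 3; log2 fold change 1.03, SE 0.32, adjusted p = 0.281). zma-miR159a-3p stood at 13742 ± 2457 and 4766 ± 1949 CPM (1.53, SE 0.47, adjusted p = 0.281). zma-miR168b-3p_R+1 stood at 1588 ± 760 and 652 ± 65.9 CPM (1.28, SE 0.46, adjusted p = 0.371).

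From 53 h to 78 h, 0 of 219 sequences were higher and 0 lower by the edgeR quasi-likelihood test, with 17 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma voom. A fit with the replicate block called 0. Libraries did not overlap for 11.4%, where chance gives at most 10%. When adjusted over the list alone, 2 of the 4 small RNA pathway sequences and 2 of the 12 GAMYB and TCP targeting sequences were higher. Of the families and lists 0 passed, with a lowest camera adjusted p of 0.0843 for meristem and growth factors and for NF-YA targeting.

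GA3-treated embryos at 53 h were compared with the untreated late line at the later time of 78 h. The 15 copper and redox sequences had a median log2 fold change of -0.27 and the 12 GAMYB and TCP targeting sequences of -0.04, with 0 past the test in either list. Of 219 sequences 0 were called by the edgeR quasi-likelihood test, 12 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0. Libraries did not overlap for 10.5%, where chance gives at most 10%. Of the families and lists 0 passed; the unnamed candidates had a camera adjusted p of 0.0559, of 0.025 with RLE scaling, 0.0404 with the replicate block and 0.900 with an estimated correlation.

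GA3-treated late-line embryos were also compared with the early line at 53 h, the line whose germination is faster without treatment. Of the 15 copper and redox sequences 8 were higher with GA3 and 7 did not pass (camera adjusted p = 4.10e-07, and 0.201 with an estimated correlation). zma-MIR397b-p3 stood at 9431 ± 4510 CPM with GA3 and 499 ± 514 CPM in the early line (SD, n = 3; log2 fold change 4.23, SE 0.75, adjusted p = 0.002). zma-miR397a-5p and zma-MIR408a-p5 were listed at 0 in the early line, at least 5.24-fold and 3.72-fold lower. bdi-MIR444d-p5_1ss2GA was listed at 0 with GA3, at least 52.7-fold lower, and the unnamed candidate PC-5p-18068_190 at least 19.9-fold lower.

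Of 219 sequences 10 were higher and 5 lower with GA3 than in the early line by the edgeR quasi-likelihood test. By this test 65 had an unadjusted p under 0.05, and libraries did not overlap for 37.9%, where chance gives at most 10%. All 10 and all 5 were also called between the untreated late line and the early line at 53 h, a comparison that shares the early-line libraries. The 15 copper and redox sequences had a median of 3.98, or 2.39 with sequences at 0 set to their bound, and 13 were higher when adjusted over the list alone. The families miR397 (4.27), miR408 (2.98), miR528 (2.59) and miR393 (1.60) were higher. The 15 calls fell to 7 without early-line replicate 1 or replicate 3, to 9 without GA3 replicate 2 and to 8 without GA3 replicate 3. Without either of these early-line replicates miR408, miR528, miR393 and PC-5p-18068_190 lost their calls, and without GA3 replicate 3 so did miR408 (2.91), miR528 (2.45) and miR393 (1.55). They rose to 25 in a model with the compared groups alone, to 32 with DESeq2 and to 48 with limma voom.

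Whether the GA3 effect runs along with other changes was examined across the 219 sequences, which are not independent replicates, for 3 relations. The log2 fold changes under GA3 correlated with those over time in the early line, which share no library with them (Pearson r = 0.336, Spearman rho = 0.433), where simulated unchanged groups gave r between -0.126 and 0.158. They correlated at r = 0.541 (rho = 0.523) with the change from 53 h to 78 h and at r = 0.402 (rho = 0.480) with the early line minus the late line at 53 h. Both of these share the untreated 53 h libraries, and unchanged groups simulated against the same controls gave r from 0.352 to 0.636 and from 0.346 to 0.623, which held both values. These draws were unpaired; with like-numbered libraries at 53 h and 78 h drawn together, at the mean correlation of their residuals (0.321), the first range was 0.252 to 0.594. For 2 settings chosen after seeing the data, r with 53 h to 78 h was 0.749 over the 106 sequences with a mean of at least 100 CPM, where unchanged groups gave 0.263 to 0.679 (0.161 to 0.637 when paired), and 0.802 over 106 sequences after thinning, where they gave 0.245 to 0.663 over 140 sequences on average (0.203 to 0.642 when paired). Under the same settings r with time in the early line was 0.350, where unchanged groups gave -0.251 to 0.209, and 0.291, where they gave -0.207 to 0.210. All these simulated ranges leave out the most extreme draws at each end. For 53 h to 78 h the largest unpaired draw was 0.770 at the minimum of 100 CPM, above the 0.749. It was 0.720 after thinning, and the largest paired draws were 0.696 and 0.670. Whether the relation with 53 h to 78 h exceeds what shared controls give was not settled, since the simulated sequences vary independently and real ones need not. The same limit holds for the simulated range beside time in the early line, where other splits of the real libraries gave an absolute r of up to 0.318. In the draws over all 219 sequences, the early line at 53 h was also given the mean of the untreated late line at 53 h. The relation with time in the early line fell to 0.141 without untreated 53 h replicate 1 and to 0.213 without GA3 replicate 2, and without GA3 replicate 1 the other relations fell to 0.284 and 0.2501.

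Which transcripts carry cleavage evidence for these miRNAs was read from the degradome table, which belongs to no group and was not compared between groups. In the authors' deposited table zma-miR528a-5p had a site at position 477 of Zm00001d021850_T001 (term electron carrier activity) with 3852 reads, category 0 and p = 0.00593. zma-miR408a_L-1 had a site at position 341 of Zm00001d028486_T001 (electron carrier activity) with 12 reads and p = 0.00977 in the same deposited table. For zma-miR160a-5p, whose targets are auxin response factors, the authors' table lists sites in Zm00001d017284_T001 with 72 reads, in Zm00001d051172_T001 with 61 reads (p = 0.00652 each) and in Zm00001d014013_T001 with 324 reads (p = 0.0490), all with the term auxin-activated signaling pathway. The authors' table also lists a site of zma-miR159a-3p in Zm00001d036551_T001 (DNA binding) with 13 reads and p = 0.0118, and a site of zma-miR444a in Zm00001d050897_T001 with 93 reads and p = 0.0221. A site of zma-miR393a-5p_R-1 in Zm00001d025268_T007 (auxin-activated signaling pathway) had 7 reads in the deposited table. Of the 37 named sequences, 12 had such a site of category 0 or 1 at a deposited p under 0.05.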

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

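The degradome library, a sample in none of the 6 groups and outside every comparison, was singled out because it holds sites at a low deposited p. The authors' deposited table gives 5198 pairs of a small RNA and a transcript site with detected cleavage. Of these, 270 had a p under 0.05, for 61 small RNAs. The authors do not describe this p as adjusted, and whether 270 of 5198 exceeds the number expected by chance was not tested. The 270 pairs fall on 111 distinct sites in 110 transcripts, isoforms counted apart. Of the 270 pairs 234 were of category 0 and 36 of category 1, and 0 belonged to unnamed candidates. By family, miR171 had 41 pairs on 7 distinct sites, miR169 had 36 on 11, miR159 had 30 on 6, miR444 had 24 on 7, miR319 had 22 on 11, miR167 had 21 on 13 and miR160 had 20 on 14. The library has no control sample and no replicate, and which embryos it came from is not given in the sources used here, so no explanation was weighed.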

How the results depend on the processing

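Of the named miRNAs and families past the threshold (64 results), no setting turned a direction: of 653 values under other settings 612 also passed and 41 did not, and of 384 values with a replicate left out 263 passed and 121 did not. Depth and spread between libraries limit what could be called: most simulated 4-fold changes were missed. Except where a cause is given, the cause was not tested. Without the low-count filter, which tests more sequences, counts were 2 for GA3 at 53 h, 41 for the lines at 53 h, 7 for time in the late line, 4 for 53 to 78 h and 24 for GA3 against the early line. DESeq2 gave 28 and 50 for the lines at 6 h and 53 h, 12 for time in the early line and 32 for GA3 against the early line, and limma voom gave 46, 75, 26, 48 and, for 53 to 78 h, 1. A model with the compared groups alone gave 1 for time in the late line and 25 for GA3 against the early line. Chosen after seeing the data, thinning gave 7 for time in the early line, and leaving out the late line's replicates 3 at 6 h and 53 h (fewer samples) gave 8 for the lines at 6 h and 2 for time in the late line. The replicate block gave 11, 17, 4, 4 and 13 calls for the lines at 6 h and 53 h, time in the early and the late line, and GA3 against the early line. For time in the early line these did not include zma-miR166b-5p. For families, RLE scaling and DESeq2 gave 7 each at 6 h, and DESeq2 gave 14 at 53 h and 8 for GA3 against the early line. For lists, an estimated correlation gave 0 in the 5 comparisons with a call. Library totals alone gave 1 list for the lines at 6 h, 2 for time in the early line, 1 for 53 to 78 h and 2 for GA3 against the early line. The replicate block and RLE scaling each gave 1 for GA3 against 78 h. The correlation of GA3 with 53 to 78 h was 0.749 at a mean of at least 100 CPM and 0.802 after thinning, with the early line 0.487 and 0.507, and with time in the early line 0.350 and 0.291, all chosen after seeing the data; the planned minimum of 10 CPM removed no sequence. At a deposited p under 0.01 the degradome table gave 23 of 5198 pairs of a small RNA and a transcript site, on 12 distinct sites. Among 25 named results not past the threshold, signs turned under GA3 at 53 h for zma-miR166a-3p (0.0339 with totals, 0.0189 with named miRNAs alone, 0.0518 with 1 entry per sequence), zma-miR408a_L-1 (0.0679, 0.0479 and 0.0911, and 0.268 without those replicates 3), osa-miR444f (0.0121 without those replicates 3) and zma-miR2118b (0 after thinning, at 5.71 CPM with GA3). With a replicate left out, ranges of calls were 0 to 0 for GA3 at 53 h, 53 to 78 h and GA3 against 78 h, 7 to 12 and 8 to 24 for the lines at 6 h and 53 h, 3 to 13 and 2 to 4 for time in the early and the late line, 7 to 22 for GA3 against the early line and 0 to 5 for the interaction. For families they were 0 to 0 for GA3 at 53 h, 53 to 78 h, GA3 against 78 h and the interaction, 1 to 7 and 1 to 10 for the lines, 0 to 1 and 0 to 2 for time, and 1 to 7 for GA3 against the early line. For the correlations they were 0.284 to 0.632 (53 to 78 h), 0.2501 to 0.425 (early line at 53 h) and 0.141 to 0.335 (time in the early line). Log2 fold changes under GA3 whose sign turned with a replicate left out ranged from -0.575 to 0.227 for PC-5p-5182_671, -0.213 to 0.138 for zma-miR166a-3p, -0.411 to 0.0392 for zma-miR169o-5p_R-1, -0.720 to 0.0824 for zma-miR169a-5p, -0.191 to 0.0121 for osa-miR444f, -0.196 to 0.268 for zma-miR408a_L-1, -0.665 to 0.0384 for zma-MIR397b-p5, -0.268 to 0.851 for osa-MIR2118e-p3_2ss13TA19CT, 0 to 4.50 for zma-miR2118b and -0.257 to 0.052 for zma-miR393a-5p_R-1.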

Other observations

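Of the 8 phase change sequences (miR156 and miR529, which target SPL transcription factors, and miR172, which targets AP2 factors) 0 passed in any of the main comparisons, and 8 of 8 had a positive log2 fold change over time in the late line (median 0.98, camera adjusted p = 0.834). Of the 15 auxin signalling sequences 1 was higher in the late line at 53 h (zma-miR393a-5p_R-1) and 14 did not pass. Of the 28 meristem and growth sequences 1 was higher in the late line at 53 h, a miR166 variant, and 27 did not pass (median 0.80, camera adjusted p = 0.168). Of the 16 NF-YA targeting sequences 1 was lower at 6 h, and at 53 h 1 was higher, zma-miR169o-5p_R-1 at 8634 ± 255 CPM in the late and 2211 ± 1449 CPM in the early line (SD, n = 3; log2 fold change 1.96, SE 0.57, adjusted p = 0.0355), and 1 lower, bdi-MIR169c-p3_2ss14TC18GC. The former lost its call without early-line replicate 1 or 3, late-line replicate 2 or 3 or both replicates 3 of the late line at 6 h and 53 h, and with library totals (1.22), the compared groups alone (1.81) or the replicate block (1.97). The latter lost its call without any 1 of the 6 libraries. Of the 3 phosphate and sulphate sequences 1 was higher in the late line at 53 h, and of the 4 small RNA pathway sequences 0 passed in the main comparisons.

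Reproductive triggers of phased siRNAs, taken as markers of another tissue, gave 1 sequence lower in the late line at both times out of 3, zma-miR2118b at 155.7 ± 35.3 CPM in the early line at 6 h and 271 ± 9.38 CPM at 53 h (SD, n = 3). Camera did not call the list at 6 h (adjusted p = 0.443) or at 53 h (adjusted p = 0.152). The call of zma-miR2118b ended without any 1 of the 6 libraries at 6 h.

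In the weighing below, the tests of library scaling, of a sequence variant, of a rise of both strands and of rarer strands in other families were chosen after the results they measure were seen. Of the 15 copper and redox miRNAs, 6 were higher in the late line at 6 h and 9 at 53 h (camera adjusted p = 0.205 and 0.192 with an estimated correlation). The lowest list median over both times and 4 scalings was 2.42, and after thinning each library to the same total the lower of the medians was 2.86 over 11 members; over members with reads in both groups, the lowest was 1.43 with library totals at 6 h, where the median of all sequences was -1.03. This argues against scaling and depth as the whole cause. Of 13 members higher by more than 1 on the log2 scale at both times, 9 had any reads in the early line. Each of these 9 had reads in at least 3 of the 6 early-line libraries. For those 9 this argues against a variant that removes the listed sequence from the early line. A variant at 1 of several precursors that share a sequence, or outside the listed sequence, could lower reads without removing them and was not tested. For the other 4, at 0 in all 6, a variant and a low level cannot be told apart. Of these, 0 had a partner within 2 differing bases that was listed in the early line alone. A variant sequence could still be missing from the table. A difference between the lines in copper supply or in the regulation of these genes may underlie the pattern and was not tested.

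Of the 5p sequences of miR159 and miR166, the 4 that rose in the early line were at 0 in all 6 libraries at 6 h and listed at 53 h in both lines, while aly-MIR166a-p5_2ss13CG20AC and zma-miR166c-5p had reads at 6 h. Expected counts at 6 h were taken at the 53 h level of the sequences called in each line, so zma-miR166b-5p entered for the early line alone. Their median was 88.1 (14.0 to 342.8 over sequences and libraries), against a smallest listed total of 4 in most libraries. However, the sequences were taken because they passed with 0 at 6 h, which favors a 53 h level above listing. Expected counts under 4 were thus unlikely from the start. The values are no evidence on depth or the listing minimum beyond the calls themselves. After thinning the late-line call of zma-MIR159f-p5 ended (adjusted p = 0.0545 by the edgeR quasi-likelihood test). The 3p strands of these families had a median log2 fold change from 6 h to 53 h of 0.12 in the early and 0.31 in the late line, over 16 sequences. This argues against a rise of both strands by a like fold. It cannot speak to a gain of like amounts on both strands, which would hardly move the abundant 3p strand. In early line 53 h replicate 1, zma-miR166a-3p had 72847 counts and zma-miR166a-5p 46, and zma-miR159a-3p had 3530 and zma-miR159a-5p_R-1 311. Of the 3p sequences 1, zma-MIR159h-p3, was also at 0 in all 6 libraries at 6 h and listed in all 6 at 53 h (adjusted p = 0.0579 in the early and 0.0954 in the late line by the edgeR quasi-likelihood test). Whether rarer strands rise more in general stayed open: in other families the rarer strand had the larger log2 fold change in 9 of 17 in the early and 10 of 16 in the late line, and a value above 0 in 6 and 5 of these. A change in strand loading or stability could give the pattern and was not tested.

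Of all 527 sequences, 7 were listed in at least 5 of the 6 early-line libraries and in 0 of the 12 late-line libraries, among them bdi-MIR444d-p5_1ss2GA, and 4 in at least 10 late-line libraries and 0 early-line libraries, among them zma-miR397a-5p. Of these 11, 0 had a partner within 2 differing bases that was listed in the opposite line alone. For those with no near sequence at all, this argues against reads passing to a near-identical sequence of the table. zma-miR397a-5p and zma-MIR408a-p5 each had 1 near sequence outside this rule, and passing of reads to it was not tested. A variant with more differences, loss of the locus or a difference in expression remain candidate explanations, and no genome of either line was used here.

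Other splits of the same libraries show how often regrouping gives as many calls. With 10 splits per pair of groups, a share under 0.05 cannot be reached. For sequences the real split and the highest other gave 16 and 0 calls for the lines at 6 h, 23 and 0 at 53 h, 4 and 0 for time in the early line, 4 and 1 for time in the late line and 15 and 0 for GA3 against the early line, and 1 of 10 splits was as large in each. For GA3 at 53 h (0 and 0), 53 to 78 h (0 and 1) and GA3 against 78 h (0 and 0), all 10 were as large. For families the values were 3 and 0, 8 and 0 and 4 and 0 for both line comparisons and GA3 against the early line (1 of 10 as large), 1 and 1 for time in the late line (2 of 10), and 0 in the real split of the others, with 0 or 1 as the highest other (10 of 10). For lists other splits called more than the real ones: 2 and 4 for the lines at each time, 1 and 4 for time in the early line and 1 and 3 for GA3 against the early line (6 of 10 as large), 2 and 4 for time in the late line (9 of 10), and 0 against 5, 4 and 2 for GA3 at 53 h, 53 to 78 h and GA3 against 78 h (10 of 10). Members of a list vary together between libraries (estimated correlation up to 0.642), so list calls carry little weight here. For the interaction 100 drawn splits were all as large as the real 0, with highest others of 15 sequences, 5 families and 4 lists; with 0 real calls no other share was possible. For the correlation of the GA3 effect with time in the early line, 1 of 100 joint splits, the real one, was as large (0.336, highest other 0.318). The time change has calls of its own, and GA3 alone has 10 splits, with which a share under 0.05 cannot be reached. The correlation was 0.350 at a mean of at least 100 CPM and 0.291 after thinning, above the largest value of simulated unchanged groups (0.272 and 0.279). Sequences vary independently in these simulations and real ones need not, so the simulated ranges may be too narrow. Without untreated 53 h replicate 1 the correlation was 0.141, inside the range of -0.126 to 0.158 of such groups, so it depends on that library, and its cause was not tested.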
